A study of Homo sapiens with 2 samples.

How the data were processed

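Microplasts are cell fragments. Per the labels, cells of the breast cancer line MCF-7 were cultured for 48 h in 50% macrophage conditioned medium and detached with trypsin, and fragments were enriched by low-speed differential centrifugation and pelleted at 1000 g for 5 min. Total RNA of 2 biological replicates was selected for poly(A) tails and made into unstranded paired-end TruSeq libraries, which were read for 100 nt on an Illumina HiSeq instrument. Selection for poly(A) removes most histone messages and RNA without a tail, and without strand the reads of a gene and its antisense partner cannot be told apart.

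The deposited values are raw counts per gene in 1 table per library, which the authors made, per the submitters' processing notes, with FastQC, Trimmomatic, STAR and HTSeq on hg38, also named GRCh38. Versions and settings of these tools and the annotation release are not given in the sources used here. Every one of the 58721 gene identifiers, version included, is found in GENCODE release 29, which gave symbols, types and coordinates. The 5 special HTSeq rows name no gene and were left out of library sizes. Of all counted reads or pairs, 5.78% in replicate 1 and 1.88% in replicate 2 lay in no annotated feature, 9.71% and 9.99% were ambiguous between genes and 6.99% and 8.72% did not align uniquely. Genes that overlap another annotated gene, or that have a near-identical copy, lose reads to the last 2 classes, so their levels are uncertain and can be too low. Levels are not divided by gene length unless stated.

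CPM values (counts divided by the library total and scaled to a common total) were computed over the 16010302 gene-assigned counts of replicate 1 and the 16618955 of replicate 2. Levels are given as mean ± SD over the 2 libraries, or per library. Shares carry 95% Clopper-Pearson intervals, and the limit that a count of 0 allows is 3 counts of the total. Intervals of a gene's log2 difference are exact binomial intervals of its counts in the 2 libraries, and all of these cover counting error only, since reads from amplified libraries are not independent molecules. Sex-marker genes were left out of the gene tables.

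With 1 group of 2 libraries no comparison between conditions can be made, and no p-value is reported. Differences are coded as replicate 2 minus replicate 1, on CPM scaled by the TMM factors of edgeR 4.0.16 (1.27 and 0.787) with a pseudocount of 0.5, and genes were counted where the mean was at least 5 CPM and the difference at least 2-fold. This is a fixed rule of size, not a test. The biological coefficient of variation came from edgeR's common dispersion with an intercept alone after filterByExpr with a minimum count of 10. DESeq2 1.42.0 served as an alternative for scaling and dispersion. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

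A set of 29 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The lists held 658 entries, of which 656 matched a gene, 15 of them through the current symbol. They cover the mitochondrial genome, ribosomal proteins, oxidative phosphorylation, glycolysis, chaperones, the unfolded protein response, hypoxia, p53, apoptosis, immediate early genes, proliferation, histones, actin and motility, vesicles and membrane repair, nuclear-retained RNAs, epithelial, mesenchymal and stem cell markers, oestrogen targets, genes amplified or deleted in MCF-7, metalloproteinases, inflammatory, interferon and receptor genes, and markers of leukocytes, stroma and blood. The median log2(CPM + 1) of each list was ranked among 10000 random lists of the same size from 19940 protein-coding genes. The median log2 difference, over members with a mean of at least 1 CPM, was ranked among 10000 lists matched on level in 20 bins. Lists at a percentile of at least 97.5 were called high, or higher in replicate 2, and those at most 2.5 low, or higher in replicate 1. These percentiles describe these libraries and are not tests across replicates.

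The named genes are the 20 with the highest mean CPM, up to 4 of the highest members of each list, the lowest members of lists mostly under 1 CPM, all members of the lists with few members, the 10 genes furthest in each direction between replicates, a set of markers (CDH1, CDH2, VIM, KRT8, KRT18, ESR1, CDKN2A and MTAP) and the 5 highest non-coding genes other than sex markers. Other list members were named for their difference or known role, after their values were seen. Alternatives covered DESeq2 size factors, no scaling, filters on low counts, pseudocounts, gene length, the background of the random lists and each library alone. A quadratic fit of the difference on GC content and log2 transcript length and the omission of mitochondrial genome genes were added after the data were seen.

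The calculations were tested on simulated data. With 14289 genes and no change, a coefficient of variation of 0.3 was recovered as 0.292. With 200 changed genes among 10691 and a coefficient of variation of 0.1, the rule of size called 95.0% of the 4-fold genes and 2.0% of the 1.5-fold genes. At a coefficient of variation of 0.38, the estimate from these libraries, it called 81.0% of the 4-fold genes, 22.0% of the 1.5-fold genes and 19.9% of the unchanged genes, over 10647 genes, so a gene it counts is not thereby shown to differ beyond the spread between replicates. At the coefficient of 0.1, none of the 29 lists was called without a change, a list of 20 genes changed 1.5-fold lay at percentile 100, and 3 of 40 random lists were called in level. These list checks were not made at 0.38, and the simulated genes varied independently of each other. They therefore do not give the rate at which lists would be called without a change in these libraries.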

Results

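The series held 2 RNA sequencing libraries of microplasts, which are cell fragments, collected by low-speed differential centrifugation from cells labelled MCF-7, an oestrogen receptor-positive human breast cancer line. The cells had been kept for 48 h in 50% macrophage conditioned medium. The labels call the libraries biological replicates of 1 group, and no library of whole cells or of untreated cells was analysed here. The values below therefore describe the RNA of these fragment preparations and the difference between the replicates, without a test between conditions and without p-values. Replicate 1 had 16010302 gene-assigned counts and replicate 2 had 16618955. A count of 0 allowed a level of up to 0.187 CPM (counts scaled to a common library total) in replicate 1 and 0.181 CPM in replicate 2.

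The fragment preparations held polyadenylated RNA of a large part of the protein-coding genome. No value analysed here separates RNA of the fragments from that of any whole cells left among them. Of 19940 protein-coding genes in the table, 12645 reached 1 CPM in replicate 1, 11817 in replicate 2 and 11767 in both. Genes of the mitochondrial genome took 5.40% of the gene-assigned counts in replicate 1 (95% Clopper-Pearson interval 5.39 to 5.41) and 11.75% in replicate 2 (11.73 to 11.76), a mean of 8.58% ± 4.49 (SD, n = 2). Cytosolic ribosomal protein genes took 9.002% and 11.2%. Long non-coding RNA genes took 1.19% in replicate 1 (1.188 to 1.199) and 0.437% in replicate 2 (0.434 to 0.440). The 10 genes with the highest mean level took 6.45% and 12.5%.

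The most abundant transcripts came from the mitochondrial genome, the translation machinery, the actin cytoskeleton and glycolysis. MT-CO1, a subunit of cytochrome c oxidase (mitochondrial genome, positions 5904 to 7445 of GRCh38), had the highest level, 17657 ± 12126 CPM (mean ± SD, n = 2, as for the levels that follow). The large mitochondrial ribosomal RNA MT-RNR2 had 14183 ± 6285 CPM and the translation elongation factor EEF1A1 11465 ± 3435 CPM. They were followed by MT-CO2 at 10530 ± 4804, MT-ND4 at 9016 ± 4448 and the cytoplasmic actin ACTG1 at 8022 ± 731 CPM. The elongation factor EEF2 had 6894 ± 1944 CPM, MT-CO3 6269 ± 3662 and the chaperone HSP90AA1 5821 ± 2964. The other genes among the 20 highest lay between 3470 and 4745 CPM. They were MT-ND5, MT-ATP6, MT-CYB, MT-RNR1, the ribosomal protein genes RPS4X, RPL8 and RPL4, the glycolytic enzyme gene ENO1, ACTB, GNAS and HNRNPA2B1. Among non-coding genes outside the mitochondrial genome, the pseudogenes MTATP6P1 (573 ± 278 CPM) and RPS2P5 (433 ± 246 CPM) and the nuclear RNA NEAT1 (483 ± 513 CPM) were highest. Reads that fit a pseudogene and its near-identical parent gene equally well were counted for neither, and others can be misplaced. The levels of both pseudogenes are therefore uncertain.

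Which groups of genes were well represented was asked with 29 gene lists, each set against 10000 random lists of the same size drawn from protein-coding genes. The median levels of 12 lists were high and those of 3 were low. Without a library of whole cells, a high level does not show that a group is enriched in fragments or induced. When the random lists were drawn only from genes with at least 1 CPM in a library, 10 were high and 11 low. Of the high lists, 9 lay above all 10000 random lists. They comprised the 13 protein-coding genes of the mitochondrial genome, 79 cytosolic ribosomal protein genes, 18 chaperone genes, 17 glycolysis genes, 40 actin and motility genes, 45 nuclear genes of oxidative phosphorylation, 34 proliferation genes, 28 vesicle and membrane repair genes and 11 genes amplified in MCF-7. After the genes named above, the leading members were RPS2 (3154 ± 615 CPM), the chaperones HSP90AB1 (3017 ± 377), HSPD1 (1629 ± 619) and CCT5 (1030 ± 305), and the glycolytic enzyme genes PKM (3136 ± 1736), GAPDH (2449 ± 1238) and TPI1 (1274 ± 410). The actin-binding filamin gene FLNA had 1502 ± 994 CPM and cofilin, CFL1, 896 ± 239. The subunits of ATP synthase ATP5F1B and ATP5F1A had 1256 ± 351 and 630 ± 181 CPM, UQCRH 571 ± 69.6 and ATP5F1E 519 ± 170. The replication licensing genes MCM7, MCM3 and MCM4 had 812 ± 221, 466 ± 31.6 and 350 ± 43.2 CPM, and MKI67, a marker of cycling cells, 347 ± 131. Annexin genes led the vesicle list, with ANXA2 at 423 ± 123 and ANXA5 at 371 ± 50.8 CPM, beside RAB7A at 294 ± 44.6 and the tetraspanin gene CD63 at 252 ± 51.7.

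Stress and signalling genes were also among the high lists. The 24 genes of the unfolded protein response, which handles misfolded protein in the endoplasmic reticulum, lay at percentile 99.99. They were led by HSPA5 (979 ± 582 CPM), CANX (861 ± 207), CALR (829 ± 66.3) and ATF4 (807 ± 424). The 17 immediate early genes, transcribed within minutes of a stimulus, lay at percentile 98.9 with JUNB at 558 ± 490, EGR1 at 402 ± 365, JUN at 252 ± 235 and IER2 at 200 ± 162 CPM. The 26 apoptosis genes lay at percentile 98.0, with PARP1 at 900 ± 437, PMAIP1 at 232 ± 176, MCL1 at 180 ± 125 and the death receptor gene TNFRSF10B at 151 ± 103 CPM. Neither the immediate early list (percentile 82.9) nor the apoptosis list (54.3) was called high against expressed genes alone, and the apoptosis list was not called without replicate 1 either (97.2). The hypoxia list (percentile 96.2; NDRG1 787 ± 248 CPM, PFKFB3 78.3 ± 38.6, BNIP3L 77.5 ± 22.9, KDM3A 52.5 ± 22.1) and the p53 targets (92.7; GADD45B 130 ± 108, MDM2 114 ± 56.7, GADD45A 109 ± 86.5, CDKN1A 90.1 ± 15.6) lay within the range of random lists.

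**Figure D1:**
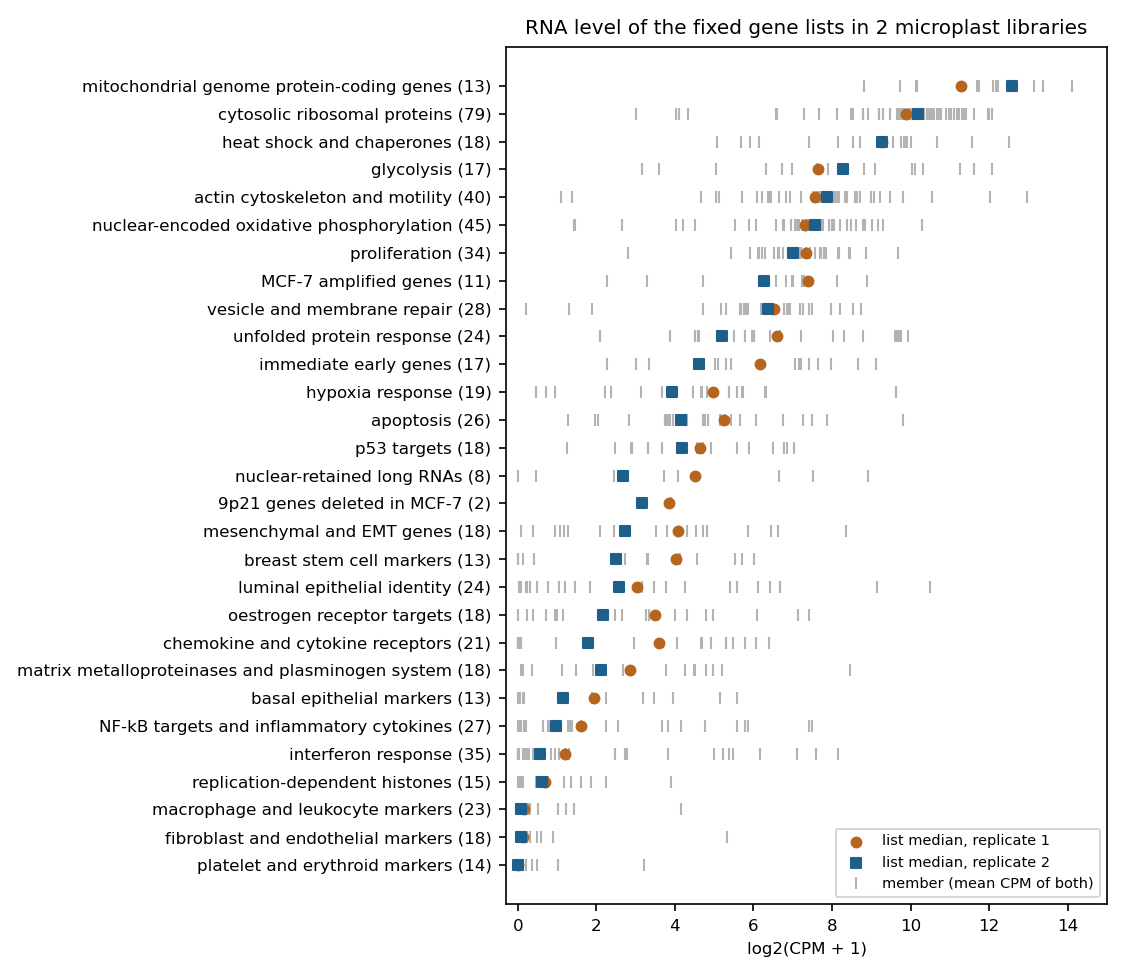
Level of the 29 gene lists in microplasts. Each row is a list with its number of members, the horizontal axis gives log2(CPM + 1), circles are the list medians of replicate 1, squares those of replicate 2 and grey ticks are members at the mean of both. The 13 genes of the mitochondrial genome have the highest median, and the platelet and erythroid markers the lowest.

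Markers of epithelial and of mesenchymal cells were present side by side. The epithelial keratins KRT8 and KRT18 had 1443 ± 454 and 566 ± 43.2 CPM, and the epithelial adhesion gene EPCAM 101 ± 14.4. The mesenchymal intermediate filament gene VIM had 329 ± 13.7 CPM, N-cadherin (CDH2) 86.7 ± 5.73 and the matrix gene TNC 98.1 ± 33.9, whereas E-cadherin (CDH1) had 4.90 ± 0.391. XBP1 had 100 ± 87.1 CPM and ITGA5 56.9 ± 4.93. ESR1, the oestrogen receptor gene, had 5 reads in replicate 1 and 1 in replicate 2, or 0.312 and 0.0602 CPM. Its target TFF1 had 0.250 and 0.120 CPM and PGR, the progesterone receptor gene, 0.937 and 0.903. Other genes of the target list were well above this, among them MYC (170 ± 172 CPM), CCND1 (140 ± 22.9), STC2 (66.6 ± 62.6) and ADCY9 (30.5 ± 9.30). As lists, the luminal (percentile 52.5), mesenchymal (69.4), oestrogen target (51.7) and basal (31.9) genes and the breast stem cell markers (58.3) lay within the range of random lists. Against expressed genes alone the luminal (0.11), oestrogen target (0.35) and basal genes (0.04) were low. EGFR (47.3 ± 15.7 CPM), KRT17 (34.3 ± 1.13), LAMB3 (14.3 ± 2.79) and LAMC2 (10.1 ± 4.59) led the basal list, and CD44 (63.4 ± 13.2), BMI1 (50.8 ± 18.03), ITGA6 (44.8 ± 11.4) and KLF4 (22.6 ± 18.2) the stem cell list.

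Genes on which the label MCF-7 can be checked gave a mixed picture. CDKN2A and MTAP on chromosome 9, which MCF-7 cells lack, had reads in both libraries. CDKN2A (21967753 to 21995301) had 228 and 229 reads, or 14.0 ± 0.326 CPM. MTAP (21802543 to 21937651) had 199 and 72 reads, or 12.4 and 4.33 CPM. As a list of 2 they lay at percentile 63.1 in level. ESR1 and TFF1, near 0 as given above, also went against the label. Genes amplified in MCF-7 were abundant, with the kinase gene RPS6KB1 at 475 ± 68.3, TRIM37 at 277 ± 3.76, BCAS3 at 156 ± 31.1 and NCOA3 at 149 ± 42.2 CPM. These are the 4 highest of 11, and a high RNA level does not by itself show amplification. Other expressed genes of the amplified regions lay at percentile 99.9 of windows of neighbouring genes for 17q23 but 80.2 for 20q13. The libraries are called labelled MCF-7 for this reason.

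**Figure D2:**
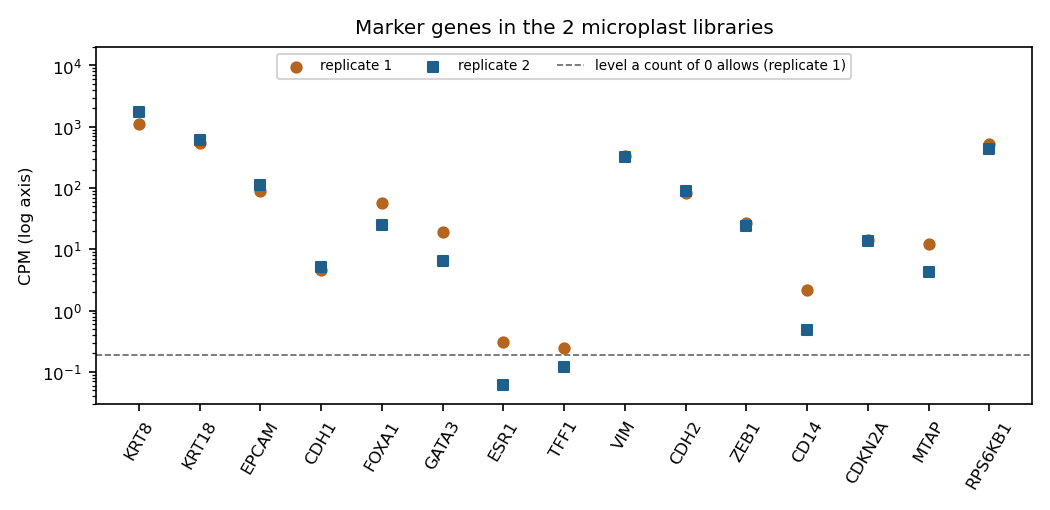
Levels of marker genes in the 2 microplast libraries. The vertical log axis gives CPM, circles are replicate 1, squares are replicate 2 and the dashed line is the 0.187 CPM that a count of 0 allowed in replicate 1. KRT8 and KRT18 stand highest, and ESR1 and TFF1 lie near the dashed line.

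Markers of other cell types were scarce. The 23 macrophage and leukocyte markers lay at percentile 1.51, the 18 fibroblast and endothelial markers at 1.30 and the 14 platelet and erythroid markers at 0.245. Of the first list, 7 members had no read in either library, including PTPRC, CD163, MSR1, C1QA and C1QB. CORO1A, a leukocyte actin regulator, had 16.8 ± 0.487 CPM, ITGAX 1.68 ± 1.61 and CD14 2.19 CPM in replicate 1 and 0.481 in replicate 2. COL1A1 at 38.8 ± 16.4 CPM was the 1 fibroblast or endothelial marker above 1 CPM, and COL1A2 and POSTN had no read. ITGA2B had 8.31 ± 7.07 CPM, while the haemoglobin genes HBA1 and HBB had no read. Genes of inflammatory signalling, metalloproteinases and histones lay within the range of random lists, but all 5 of these lists were low against expressed genes alone, at percentiles of 0.23 or less. The nuclear factor kappa B targets and cytokines lay at percentile 15.2 (NFKB2 179 ± 40.6 CPM, IER3 170 ± 127, NFKB1 57.1 ± 8.31, SOD2 54.6 ± 0.399), and chemokine and cytokine receptors at 48.2 (IL6ST 83.3 ± 7.83, IFNGR1 66.2 ± 52.5, IFNAR1 53.7 ± 10.3, TNFRSF1A 43.3 ± 28.4). Interferon response genes lay at percentile 6.57. The antigen presentation genes B2M (282 ± 101 CPM), HLA-C (193 ± 29.3) and HLA-A (136 ± 26.7) and the transcription factor gene STAT1 (70.9 ± 1.60) led them, while OAS2, CXCL11 and GBP1 had no read. Matrix metalloproteinase and plasminogen genes lay at percentile 38.9, with the inhibitor gene TIMP1 at 347 ± 178, TIMP2 at 35.6 ± 1.94, ADAM10 at 30.4 ± 16.7 and ADAM17 at 26.7 ± 0.163 CPM. Replication-dependent histone genes, whose messages mostly lack a poly(A) tail and are selected against by oligo-dT, lay at percentile 11.7 with HIST1H1C at 13.8 ± 2.10 CPM and 9 of 15 members under 1 CPM.

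The replicates shared the order of gene levels but were far apart in detail. Across 14554 genes with at least 1 CPM in a library, Pearson's r of log2(CPM + 1) was 0.952 and Spearman's rho 0.951; these are correlations across genes, which are not independent replicates. The counts differed by far more than sampling noise (chi-square per degree of freedom 132.6, 16878 degrees of freedom), so the files are not copies of a single library. That they are separate biological samples rests on the labels. The biological coefficient of variation estimated by edgeR was 0.380 over 13603 genes.

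Replicate 2 held less RNA of nuclear-retained and immediate early genes than replicate 1, and more RNA of the mitochondrial genome and of actin and motility genes. Of 10705 genes with a mean of at least 5 CPM, 1257 were at least 2-fold higher in replicate 2 and 1080 at least 2-fold higher in replicate 1 after scaling by the trimmed mean of M-values (TMM). Together these are 21.8% of the genes, and in simulated libraries with a coefficient of variation of 0.38 the same rule called 19.9% of unchanged genes. That coefficient was estimated from these same 2 libraries, so the 2 shares are close by construction. With no other estimate of the spread, the counts do not separate single genes from the spread between the replicates. The split depends on the scaling and on the filter on low counts. The share of these genes that were higher in replicate 2 was 53.8% with TMM, 65.8% with DESeq2 size factors (1608 against 837 genes) and 2.9% in CPM with no further scaling (107 against 3527). With TMM it was 45.4% at a mean of at least 1 CPM (1371 against 1650), 42.9% with no filter (1426 against 1901) and 70.8% at 20 CPM (1094 against 452). The median gene lay at a log2 difference of 0.06 with TMM and −0.61 without scaling, and the differences below are on the TMM scale, replicate 2 minus replicate 1. Of 206 long non-coding RNA genes, 71 were at least 2-fold higher in replicate 1 and 1 in replicate 2. Of 10326 protein-coding genes, the numbers were 967 and 1222.

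Among single genes, the lipid droplet gene HILPDA (chromosome 7, 128455849 to 128458418) was furthest towards replicate 1, with 57.5 against 3.97 CPM and a log2 difference of −3.04 (95% counting interval −3.55 to −2.80). TCIM (−2.97), the muscle and stress gene ANKRD1 (−2.77), RNF122 (−2.62), NOG (−2.60), MAPK15 (−2.60), SLC12A8 (−2.59) and HERPUD1, a gene of the unfolded protein response (−2.50), followed. The long non-coding RNA LINC00659 (−2.60) and the pseudogene AL390728.4 (−2.58) belong to the same 10 genes, and the second is uncertain because reads of a pseudogene can be split with its parent. RAB13 (chromosome 1, 153981617 to 153986358), a small GTPase gene, was furthest towards replicate 2, with 13.9 against 76.2 CPM and a log2 difference of 3.09 (2.94 to 3.36). The kinase gene CDC42BPG (2.64), the kinesin gene KIF1C (2.51, 128 against 454 CPM), the mitochondrial transport adaptor TRAK2 (2.37) and NQO1 (2.28) were also among the 10 highest. SNORD17 (2.70) lies inside the transcribed region of other genes, and NOMO3 (2.99), NOMO2 (2.53), EIF3C (2.55) and MTCO1P12 (2.59) share sequence with near-identical copies, so these 5 values are uncertain. Strand was not marked, and HILPDA, MAPK15, SLC12A8, AL390728.4, HERPUD1, RAB13, KIF1C, TRAK2 and NQO1 overlap other annotated genes on either strand, so their values are uncertain as well. TCIM, ANKRD1, RNF122, LINC00659, NOG and CDC42BPG overlap no other annotated gene.

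**Figure D3:**
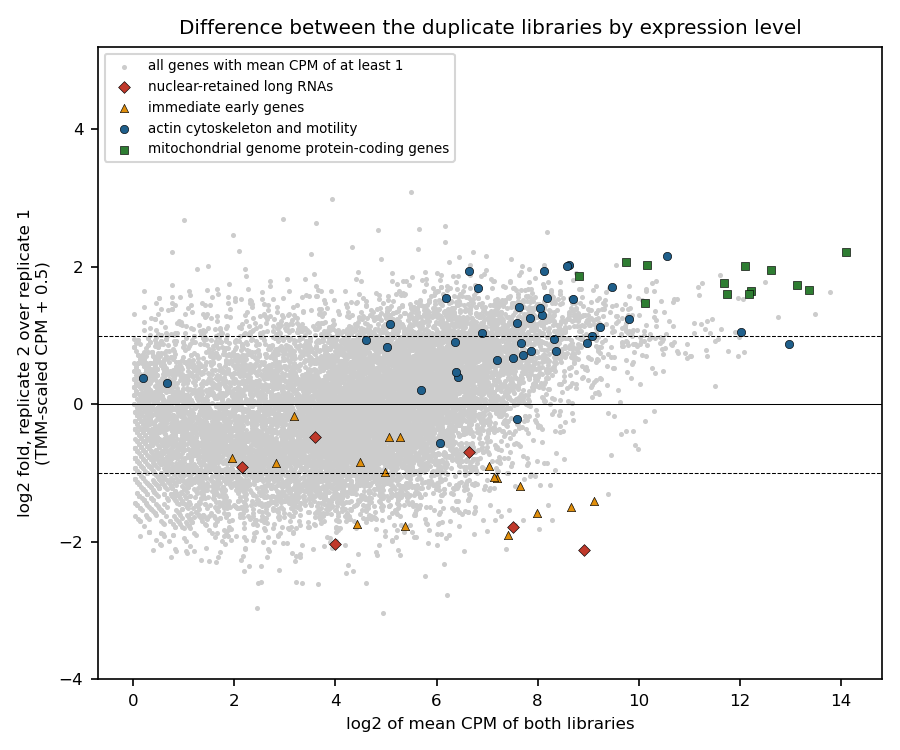
Difference between the microplast replicates for each gene. The horizontal axis is the log2 of mean CPM and the vertical axis the log2 fold, replicate 2 over replicate 1, on TMM-scaled CPM with 0.5 added. Horizontal lines mark 2-fold, and genes of the nuclear-retained, immediate early, actin and mitochondrial lists are picked out, with NEAT1 at −2.12 and MT-CO1 at 2.22.

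The medians of 7 lists lay towards replicate 1 when set against lists of like expression. All 6 measured nuclear-retained long RNAs were lower in replicate 2, with a median log2 difference of −1.35, below all 10000 matched lists. NEAT1, the RNA of nuclear paraspeckles (chromosome 11, 65422774 to 65445540), had 846 against 120 CPM (−2.12) and MALAT1 310 against 55.2 CPM (−1.79). FTX (−2.04), KCNQ1OT1 (−0.92), TUG1 (−0.69) and PVT1 (−0.48) had the same sign, MIAT had 0.687 and 0.0602 CPM and MEG3 no read. In level the list lay at percentile 68.9, within the range of random lists. The matched lists were not matched on gene type, and the 206 long non-coding RNA genes with at least 5 CPM had a median difference of −0.70. All 17 immediate early genes were lower in replicate 2 (median −1.06, below all matched lists), including MYC (−1.90, also on the list of oestrogen targets), JUN (−1.59), EGR1 (−1.50) and JUNB (−1.41). In the unfolded protein response 16 of 24 genes were lower (median −0.70, below all matched lists), with DDIT3, a gene of stress-induced death, at −2.06 and CHAC1 at −1.69. CANX (1.19) and PDIA3 (1.29) had the opposite sign. Breast stem cell markers (median −0.94, percentile 0.51; SOX2 −1.86, CD24 −1.48), oestrogen receptor targets (−0.90, percentile 0.12; STC2 −1.60) and hypoxia genes (−0.50, percentile 1.62; VEGFA −1.85) were lower in the median too. Of these lists 3 of 9 stem cell markers (CD44 0.26), 4 of 12 oestrogen targets (GREB1 1.03) and 5 of 16 hypoxia genes (P4HA1 0.56) were higher in replicate 2. The calls for the stem cell markers and oestrogen targets ended when genes under 1 CPM were included (percentiles 49.9 and 13.3), and that for hypoxia genes when a mean of 5 CPM was required (6.28). Proliferation genes had a median of 0.05 with TMM and −0.64 without scaling, and 17 of 34 members lay on either side of 0. Their mean was 0.23, and 7 members were at least 2-fold higher in replicate 2 against 3 in replicate 1. Matched lists had a median of 0.63, which placed the list at percentile 0.01. The signs of the median and mean with TMM differ from the side of the percentile for this list.

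The medians of 6 lists lay towards replicate 2. Matched lists lay on that side too, at 0.96, 0.71, 0.73 and 0.66 for the mitochondrial, actin, glycolysis and oxidative phosphorylation lists. Without scaling, the medians of these lists were 1.08, 0.32, 0.44 and 0.27 in the same order. Counts of higher members do not by themselves set a list apart. Of 79 ribosomal protein genes 76 were higher and 39 at least 2-fold so, yet that list was not called. All 13 protein-coding genes of the mitochondrial genome were at least 2-fold higher (median 1.77, above all matched lists), with MT-CO1 at 2.22 and MT-CYB at 2.01. Of 40 actin and motility genes 38 were higher and 20 at least 2-fold so (median 1.01, percentile 99.84), including FLNA (2.15) and the non-muscle myosin gene MYH9 (1.71). Of 17 glycolysis genes 15 were higher (median 1.13, percentile 99.2), led by PKM at 1.89 and GAPDH at 1.77. Of 45 nuclear genes of oxidative phosphorylation 43 were higher (median 0.96, percentile 99.88), with COX4I1 at 1.24 and CYCS at 1.13. After a fit of the difference on GC content and transcript length this list lay at percentile 74.5 and was no longer called. The 7 measured basal markers had a median of 1.05, above all matched lists, with LAMC2 at 1.57, MYLK at 1.27, ACTA2 at 1.17 and TAGLN at −0.92; including genes under 1 CPM gave percentile 97.2, which ended the call. Of 17 interferon response genes 13 were higher, with a median of 0.46 (percentile 98.4) and B2M at 1.44, but they had a median of −0.11 without scaling, and their call ended with a pseudocount of 2 (percentile 93.4) and after the GC and length fit (88.0).

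**Figure D4:**
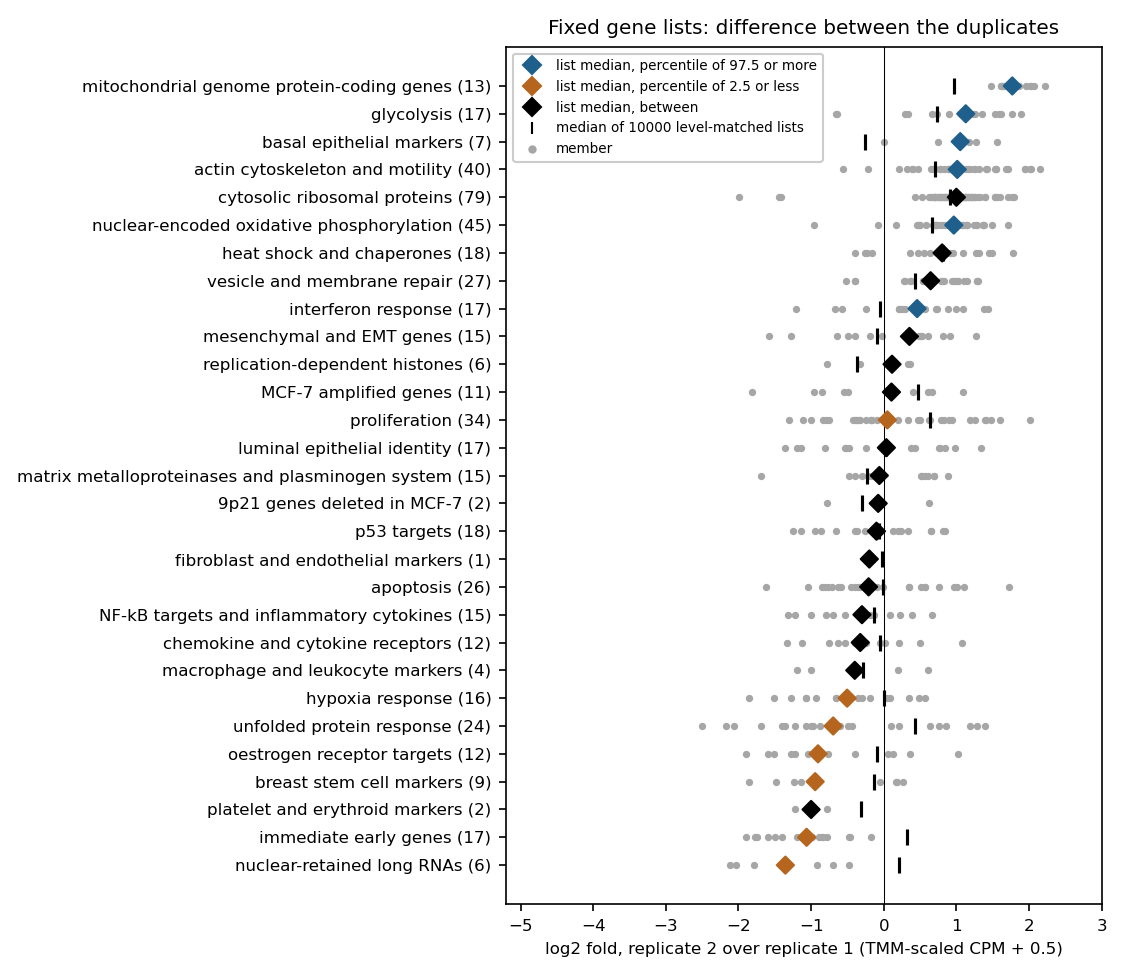
Difference between the replicates for the 29 gene lists. Each row is a list with its number of measured members, the horizontal axis is the log2 fold, replicate 2 over replicate 1, on TMM-scaled CPM with 0.5 added, grey points are members, diamonds are list medians and ticks are the medians of 10000 lists of like expression. Without TMM scaling the medians of 6 lists change sign, including proliferation and interferon response.

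The other 16 lists lay within the range of matched lists. Ribosomal protein genes had a median of 1.00 against 0.91 for lists of like level (percentile 92.5), and the list lay at percentile 99.8 with no filter and 1.36 after the GC and length fit, on opposite sides. Chaperones (median 0.80, percentile 45.7), vesicle and membrane repair genes (0.65, 88.9) and mesenchymal genes (0.35, 95.3; −0.33 without scaling) were on the side of replicate 2, the last of these lists only with scaling. After the fit vesicle genes lay at percentile 99.04 and mesenchymal genes at 98.5, past the threshold. Histone (0.11, 90.9), MCF-7 amplified (0.11, 12.9) and luminal genes (0.04, 50.0) had medians near 0 that were negative without scaling, at −0.41, −0.58 and −0.48, and luminal genes with at least 5 CPM lay at percentile 2.25, past the threshold. Medians below 0 were found for metalloproteinase and plasminogen genes (−0.06, percentile 73.8), the 9p21 genes (−0.08, 65.7), p53 targets (−0.10, 44.0), apoptosis genes (−0.21, 15.9) and nuclear factor kappa B targets (−0.30, 24.1). Cytokine receptors (−0.32, 14.96), macrophage markers (−0.40, 39.4 over 4 genes), platelet and erythroid markers (−1.0, 8.73 over 2 genes) and the fibroblast marker COL1A1 (−0.20, 41.2) completed the set.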

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

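The rule for the test on CDKN2A and MTAP and the test on genes with no read in replicate 2 were chosen after the result was seen. CDKN2A and MTAP had been named as a check of the cell line label before the data were examined. The other tests in this part were chosen before their results were seen. Reads that the gene comparisons do not use made up a sizeable part of both libraries. Of all counted reads or pairs, those in no annotated feature were 5.78% in replicate 1 and 1.88% in replicate 2, those ambiguous between genes 9.71% and 9.99%, and those without a unique alignment 6.99% and 8.72%.

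The share outside annotated features, higher in replicate 1, goes with more nuclear-retained and short-lived RNA there. Genomic DNA in replicate 1 as the whole cause of the excess of these RNAs is argued against, since it would raise unexpressed genes as much per kilobase. Of 4521 protein-coding genes with no read in replicate 2, 77.6% had none in replicate 1. Their mean excess was 0.0142 CPM per kilobase against a median of 15.8 for 23 nuclear-retained and immediate early genes. Of the 23, 22 lay above their 99th percentile of 0.191. That count adds little, because both lists were already known to be higher in replicate 1. Whether DNA contributed to the share outside annotated features was not tested. GC content and transcript length as the whole cause are also argued against for the immediate early genes. A fit that took up 3.97% of the variance left 108.4% of their median, still below all matched lists. For the nuclear-retained RNAs 96.1% was left, also below all matched lists. That value cannot decide on length, because the fit was made on protein-coding transcripts and the lengths of these RNAs were capped. A smaller share of nucleus-containing cells in replicate 2 stays open. The 7 RNAs known from cell protrusions that had not been seen among the leading genes lay at percentile 50.1 (median 0.23), neither high nor low enough to decide. Of these, 5 were higher in replicate 2, and they ranged from CYB5R3 at 1.58 to INPP1 at −0.72. RAB13, KIF1C and TRAK2 are also protrusion RNAs but had been seen among the leading genes. With them the 10 RNAs lay at percentile 99.92 (median 1.09), which tests nothing because their side was already known. A smaller share of nucleus-containing cells cannot be told apart from a difference between the cultures or in the time before RNA extraction. The labels give nothing on either, and no biological explanation was tested.

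The oestrogen receptor gene and TFF1 lay near 0 in libraries labelled MCF-7. CDKN2A and MTAP, which MCF-7 lacks, were at 4.33 CPM or more in both libraries. These values argue against MCF-7 cells as the only source of the RNA. RNA from cells that are not MCF-7 is therefore a candidate explanation for the low oestrogen receptor gene and TFF1. Whether the libraries also hold MCF-7 RNA cannot be told from these data. Windows of 32 neighbouring expressed genes, without the members of the fixed list, lay at percentile 99.9 of 11626 windows for 17q23 and 80.2 for 20q13, regions amplified in MCF-7, so that 1 region stood out and 1 did not. A mislabelled and a mixed culture were not told apart, and no biological explanation was tested.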

How the results depend on the processing

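The GC and length fit and the omission of mitochondrial genome genes were chosen after the data were seen. The genes detected and the dispersion kept within the bounds set for them under the alternatives run. For the mitochondrial share the bound was the SD of the 2 libraries. A single library cannot leave that bound, so it decides nothing for the libraries alone. No bound was set for the duplicate check, where chi-square per degree of freedom ranged from 132.6 to 252.7. Over the libraries alone, the mitochondrial share ranged from 5.40 to 11.75 percent and the protein-coding genes detected from 11817 to 12645. The coefficient of variation ranged from 0.372 to 0.3996. Pearson's r was 0.974 with no filter, 0.899 at a mean of at least 10 CPM and 0.950 with a pseudocount of 0.1; Spearman's rho was 0.927 and 0.873 for the first 2. Genes at least 2-fold higher in replicate 2 numbered 107 with no scaling against 1257. Those higher in replicate 1 numbered 3527 with no scaling, 1650 at a mean of at least 1 CPM, 452 at 20 CPM and 1901 with no filter, against 1080, so that most genes counted were higher in replicate 1 with no scaling, at 1 CPM and with no filter. Against a background of expressed genes only, whose median is higher by construction, the lists called low went from 3 to 11 and those called high from 12 to 10, without the immediate early (82.9) and apoptosis (54.3) lists. Apart from this the causes were not tested. Of 145 list percentiles in level recomputed, 134 kept their side of the threshold, and of 173 in difference 161 did. No list called in the main setting took the opposite call. Ribosomal protein genes, not called there, lay at percentile 99.8 in difference with no filter and 1.36 after the fit, on opposite sides. The nuclear-retained RNAs are not protein-coding, and the fit was applied to them with their lengths capped at the upper end of the fitted genes. No paired analysis was possible because there is only 1 group. With 2 libraries a value without replicate 1 or 2 is that of a single library, and a two-sided exact test on 2 pairs could not give a p under 0.5. Depth limits genes near 0.18 CPM, such as ESR1 and TFF1.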

Other observations

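The families in the next paragraph were chosen after the replicate differences had been seen, and their values are descriptions with no explanation tested. Differences are replicate 2 minus replicate 1 on TMM-scaled CPM, and percentiles are among 10000 lists of like level.

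Genes of zinc finger proteins, many of them transcription factors, stood on the side of replicate 1. Of 379 with ZNF symbols, 110 were at least 2-fold higher in replicate 1 and 2 in replicate 2 (median −0.74, below all matched lists), and 31 lay above 0. Host genes of small nucleolar RNAs were on the same side in the median (18 genes, −0.80, percentile 0.04), 6 of them at least 2-fold, with SNHG3 at 164 against 34 CPM and SNHG1 at 153 against 49.6. There 3 of the 18 were higher in replicate 2, including SNHG5 (0.58), the most abundant, and SNHG6 (0.54). The 206 long non-coding RNA genes with a mean of at least 5 CPM had a like shift (median −0.70, 34.5% at least 2-fold higher in replicate 1). The shift is therefore not particular to the host genes, and the lists of like level were not matched on gene type. On the side of replicate 2 lay subunits of the proteasome (34 genes, median 0.97, percentile 97.8, PSMD2 369 against 722 CPM) and of the dynein and dynactin motor complex (19 genes, median 0.85, percentile 99.2, DCTN1 96.3 against 259 CPM and DYNC1H1 228 against 394). Medians of these 4 families kept their sign without scaling (−1.38, −1.46, 0.28 and 0.16).

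The other 6 families examined lay within the range of matched lists. They were initiation factors (46 genes, median 0.73, percentile 74.6), tubulins (11 genes, 0.42, 50.2), kinesins (36 genes, −0.08, 18.3), integrins (16 genes, 0.26, 91.7), dual specificity phosphatases (18 genes, −0.41, 13.2) and cytosolic aminoacyl-tRNA synthetases (20 genes, 0.68, 10.2). Without scaling the medians of tubulins, integrins and synthetases were −0.26, −0.28 and −0.01.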
